A study of Mus musculus with 30 samples.

How the data were processed

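Peak lists were analysed for 4 chromatin immunoprecipitation libraries of WT-MA9 mouse leukaemia cells: Menin in DMSO, Menin in MI-503, UTX in DMSO and UTX in MI-503. Per the labels' protocols, cells were harvested 4 days after treatment, fixed with 1% paraformaldehyde for 5 minutes and sonicated for 14 minutes. The concentration of MI-503 is not given in the sources used here. Each condition had 1 library among these, and the labels assign each to its antibody and treatment. The labels describe 30 libraries, of which 26 were not analysed here, among them those for other MLL complex proteins, NF-YA, histone marks, input DNA and fibroblasts. Also among the 26 are UTX libraries of WT-MA9 cells labelled Nfya-WT and Nfya-KO, in DMSO and in MI-503.

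Peaks were called with MACS2, per the submitters' processing notes, which name no version and list mm10 as the mouse build. The aligner, read filters and q threshold are not given in the sources used here. Peak names in the deposited lists pair each library with a vehicle input, which was 1 input for both Menin lists and another for both UTX lists. Each list was called on a single library, with no pooling. The deposited fold values are the ratio of the pileup at the summit plus 1 to the local background plus 1. The deposited −log10 values give the p-value and q-value of each summit. The deposited score is the whole part of 10 times −log10 q, checked in all 25651 peaks. Positions are printed from 1.

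Depth was recovered from the deposited values, since MACS2 derives each fold and p-value from a pileup and a background. Solving both for each peak gave pileups that were whole multiples of a single step, within 0.01 of a step, in all 300 peaks tried per list, or in every peak of the shorter lists, and in at most 60.8% of them at any other step tried. That step, and the step of the backgrounds, gave library reads over input reads of 0.815 for Menin DMSO, 1.35 for Menin MI-503, 1.14 for UTX DMSO and 0.737 for UTX MI-503. The values of 0.815 and 0.737 rest on the background step, of which 47.6% of Menin DMSO and 27.9% of UTX MI-503 backgrounds were whole multiples, against at most 25.4% and 11.0% at any other step tried. Backgrounds that MACS2 takes from wider windows need not be whole multiples. The pileup steps alone, without the backgrounds, put the Menin MI-503 library at no less than 1.35 times the DMSO library, and the UTX DMSO library at no less than 1.14 times the MI-503 library. A second route through the lowest background and narrowest peak gave ratios of 1.63 for Menin, where the MI-503 list has only 8 peaks to set them, and 1.55 for UTX. Absolute depth is unknown, so no limit on undetected peaks was computed. On simulated pileups, the background was recovered within 1% in 100% of 500 rows for each scaling. Each simulated background was the lowest value or a whole multiple of the step. Backgrounds from wider windows and lists as short as 8 peaks were not simulated, so the depth ratios were not checked under those conditions.

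Overlap meant at least 1 shared bp, and each observed share was set beside 100 random placements of the other list on its own chromosomes, within the stretch covered by annotated genes. Exact Clopper-Pearson 95% intervals cover counting error only, since neighbouring peaks are not independent and there are no replicates. No p-value was computed between conditions or across genes. The planned analysis used transcription start sites, but the gene table (RefSeq, GRCm38.p6, the assembly of mm10) has no strand. A summit within 1 kb of an annotated start or end of any of 21887 protein-coding genes was used in its place. The planned comparisons of CCAAT sites and of promoters matched on CpG content need the genome sequence and were not run. As a check of the code, 11182 Menin DMSO peaks were copied, with a part left out and the rest moved by less than their width. The overlap code found 100% of the kept peaks, which still overlapped by construction. It also found 100% of 300 genes with a planted summit.

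Gene lists (18 by name and 7 families by symbol pattern) were fixed before the data were examined, and 381 of the 383 names matched the gene table. Each list's share with a peak was ranked among 10000 random lists of protein-coding genes of the same size. Genes named were, by a rule fixed at the same time, up to 10 genes with a peak per list in the order of the list and any gene stated to lack a peak; the 10 boundary peaks with the highest −log10 q for Menin DMSO and for UTX MI-503; the 10 genes ranking highest in both; the 5 highest genes with a peak in 1 list alone; all 8 Menin MI-503 peaks; and the 10 highest UTX DMSO peaks. Predicted genes with Gm or Rik symbols were counted but not named, and some genes that the rule takes are not reported here. Alternatives covered the q and fold thresholds, the definition of overlap, the window, the gene set and the length of the lists. Leaving out peaks on input-rich ground, meaning a recovered background at least 3 times the lowest of the list, was added after seeing the data. Computation used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.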

Results

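Chromatin immunoprecipitation followed by sequencing was used to map Menin and UTX in WT-MA9 cells, a mouse acute myeloid leukaemia line that stably expresses the MLL-AF9 fusion. Menin, encoded by Men1, is a scaffold protein that holds the MLL1 and MLL2 histone methyltransferase complexes on chromatin. UTX, encoded by Kdm6a, is a histone H3 lysine 27 demethylase and a subunit of the related MLL3 and MLL4 complexes. MI-503 is a small molecule that blocks the contact between Menin and MLL1, and DMSO was the vehicle. Cells were harvested 4 days after treatment. The peak lists of 4 libraries were analysed, for Menin and UTX each in DMSO and in MI-503. With 1 library analysed per condition, no comparison between conditions here has a replicate check. The labels describe 30 libraries in all, and the other 26 were not analysed here. They include a further DMSO and MI-503 pair for UTX, in WT-MA9 cells labelled Nfya-WT. Fold enrichment and −log10 q of each peak are the authors' own values. They were used to describe, rank and filter peaks within a list, and the fold and p-values also to recover relative depth.

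The comparison of vehicle with MI-503 asked where each protein was found on chromatin before and after the Menin-MLL contact was blocked, which the series title describes as a switch between MLL complexes. The Menin list held 11195 peaks in DMSO and 8 in MI-503. The UTX list held 217 peaks in DMSO and 14231 in MI-503. With both antibodies, the shorter list came from the deeper library. The pileups and backgrounds behind the fold values put the Menin MI-503 library at 1.65 times the reads of the Menin DMSO library. They put the UTX DMSO library at 1.55 times the reads of the UTX MI-503 library. The pileups alone put these ratios at no less than 1.35 and 1.14. Absolute read numbers are unknown. The narrowest peak, which MACS2 sets by its fragment length, was 179 bp in the Menin DMSO and UTX MI-503 lists, 127 bp in the UTX DMSO list and 62 bp in the Menin MI-503 list. Peaks of the longer lists were narrow, with a median width of 272 bp for Menin in DMSO and 264 bp for UTX in MI-503. Their median fold enrichment was 5.87 and 7.11.

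**Figure D1:**
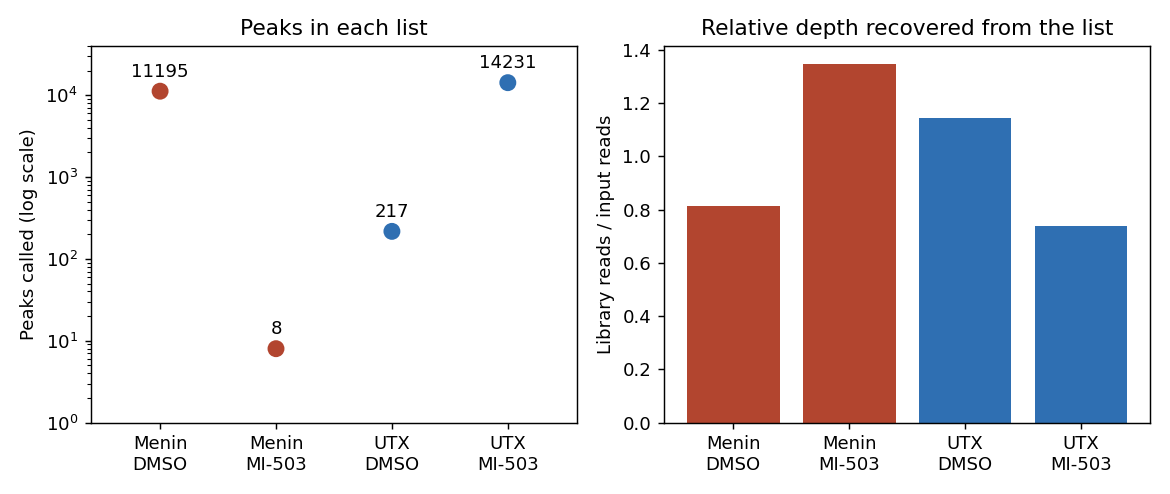
Number of peaks in each list on a log axis (left) and reads of each library relative to its input, recovered from the peak values (right), with 1 library per point or bar. The lists of 11195 and 14231 peaks came from libraries with 0.815 and 0.737 times the reads of their inputs, and the lists of 8 and 217 peaks from libraries with 1.35 and 1.14 times.

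The highest Menin peaks in vehicle lay at Tpst2, a tyrosylprotein sulfotransferase gene, Zfpm1, which encodes the GATA cofactor FOG1, Trappc2l, a vesicle trafficking gene, and Kdm1b, a histone demethylase gene. Tmem123, the deubiquitinase gene Usp28, Abtb1, the kinase gene Ripk2, the ADP-dependent glucokinase gene Adpgk and the sorting nexin gene Snx8 completed the 10 highest peaks at gene boundaries. The Tpst2 peak (mm10, chromosome 5, 112276152 to 112276936) had a fold enrichment of 46.2 and a −log10 q of 258.8, and its summit lay 160 bp from the gene's annotated boundary. The Zfpm1 peak (chromosome 8, 122281071 to 122282205) reached 42.3-fold, and the Kdm1b peak (chromosome 13, 47042970 to 47043744) reached 37.0-fold. All 10 were overlapped by a UTX MI-503 peak, and none by a Menin MI-503 or UTX DMSO peak.

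In MI-503, 1 of the 8 Menin peaks overlapped a Menin DMSO peak, which is 12.5% (exact 95% interval 0.316 to 52.7%). Random placements of the Menin DMSO peaks also reached 12.5% at most. The overlapped peak lay 95 bp from the boundary of Chchd7 (chromosome 4, 3938716 to 3938782), with a fold enrichment of 7.80. It had the lowest −log10 q of the list, 6.91, and a UTX MI-503 peak over it. The other 7 lay away from gene boundaries. Peaks inside Dpp9 and Myo7a had fold enrichments of 12.7 and 9.52. The nearest protein-coding genes of 4 others were Trim52, Cldn34c1, Nxph1 and Frmd4a, at least 53091 bp away, and the remaining peak was nearest to a predicted gene. The Frmd4a peak (chromosome 2, 3964520 to 3964590) sat on a local background 22.5 times the lowest of its list. The HOXA genes, Meis1 and Pbx3 had no Menin MI-503 peak.

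UTX in vehicle was mapped to few places, most of which a UTX MI-503 peak also touched. Of the 217 UTX DMSO peaks, 204 (94.0%, exact 95% interval 89.97 to 96.8%) were overlapped by a UTX MI-503 peak, against at most 1.84% in 100 random placements. The share was 13.8% where at least 50% of both peaks had to be shared, and 30.4% against the 217 highest UTX MI-503 peaks alone. The UTX DMSO peaks were also overlapped by Menin DMSO peaks at 188 places (86.6%, 81.4 to 90.9%). Both UTX lists were called against the same input library. All 170 genes with a UTX DMSO peak at a boundary had one in MI-503, and 168 had a Menin DMSO peak. Runx3, a haematopoietic transcription factor gene, and Rab26, named here after their values were seen, were the 2 without. The 10 highest UTX DMSO peaks were largely on ground rich in input reads, with 8 on a background at least 3 times the lowest of the list. Of the 10, 3 lay on chromosome 17 between 39843011 and 39848848, on backgrounds of 15.5 to 36.4 times the lowest of the list. They were at least 102298 bp from Esp38, the nearest protein-coding gene. Distances were measured to protein-coding genes only. Others were nearest to Filip1l, Zc3h7a, Pex2, Samd9l and Vmn1r77. Hjurp, which encodes the chaperone of centromeric histone CENP-A, was the only gene of the 10 with a peak at its boundary (chromosome 1, 88277508 to 88277730), at 11.2-fold and on a background 3.45 times the lowest of the list.

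In MI-503, the highest UTX boundary peak was again at Hjurp, at 43.4-fold (chromosome 1, 88277006 to 88277843) and again on a background 3.45 times the lowest of its list. It was followed by Txnip, an inhibitor of thioredoxin, at 43.6-fold, Crebrf at 50.3-fold, the lysosomal channel gene Mcoln1 at 46.5-fold, and Prkaca, which encodes a catalytic subunit of protein kinase A, at 46.0-fold. Fbxw7, a ubiquitin ligase gene that restrains MYC and Notch, had 41.3-fold enrichment. Sde2 and the splicing regulator gene Ptbp1 each had 43.8-fold enrichment. The AP-1 gene Junb had 41.2-fold, and Uqcrfs1, a respiratory complex III gene, had 42.7-fold. All 10 were overlapped by a Menin DMSO peak and 6 by a UTX DMSO peak.

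The overlap of Menin in vehicle with UTX in drug asked whether both proteins were found at the same places. UTX MI-503 peaks overlapped 7431 of the 11195 Menin DMSO peaks by at least 1 bp, which is 66.4% (exact 95% interval 65.5 to 67.3%, for counting error only). Random placements of the UTX peaks on their own chromosomes overlapped 0.456% on average and 0.590% at most. Conversely, Menin DMSO peaks overlapped 7599 UTX MI-503 peaks (53.4%, 52.6 to 54.2%), against at most 0.457% in random placements. The share was higher among peaks of higher rank. Among the lowest 10% of Menin peaks by −log10 q, 25.4% (22.9 to 28.0%) were overlapped, and among the highest 10% the share was 96.8% (95.6 to 97.7%). For UTX peaks the share went from 18.3% (16.3 to 20.4%) to 99.4% (98.8 to 99.7%). Menin peaks with a UTX peak over them had a median fold enrichment of 7.05, and those without had 4.64.

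**Figure D2:**
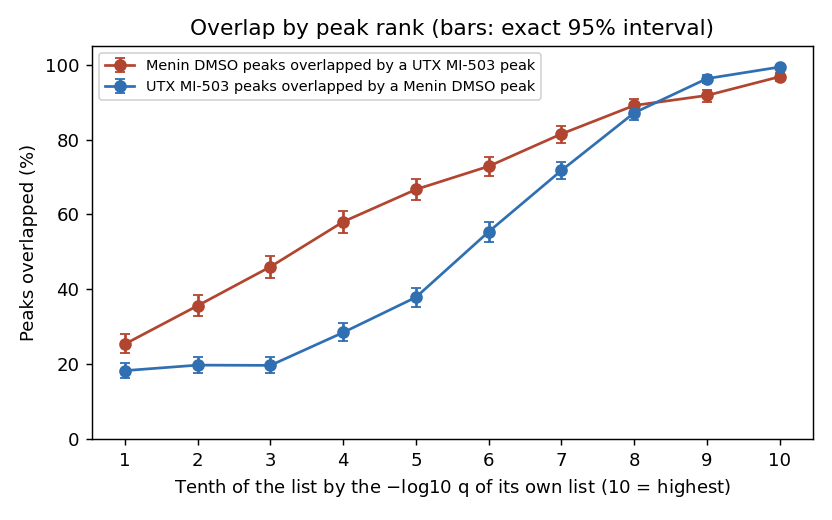
Share of Menin DMSO peaks overlapped by a UTX MI-503 peak, and of UTX MI-503 peaks overlapped by a Menin DMSO peak, in percent, in 10 equal parts of each list ordered by its own −log10 q; bars are exact 95% intervals. The shares in the highest part were 96.8% and 99.4%, and in the lowest part 25.4% and 18.3%.

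Both proteins were found chiefly at the ends of genes. The summit lay within 1 kb of an annotated start or end of a protein-coding gene for 56.3% of Menin DMSO peaks (55.3 to 57.2%) and 58.0% of UTX MI-503 peaks (57.2 to 58.8%), against at most 3.62% and 3.63% in random placements. The share was 66.4% (59.7 to 72.6%) of UTX DMSO peaks, against at most 6.91% in random placements. It was 12.5% of Menin MI-503 peaks (1 of 8, 0.316 to 52.7%), where random placements reached 37.5%. The gene table used has no strand, so starts and ends of transcription were not told apart. Among genes of at least 5 kb with a peak, 97.4% had a Menin peak at 1 boundary alone, and 96.6% had a UTX peak at 1 boundary alone. At boundaries, 86.8% (85.9 to 87.6%) of Menin peaks were overlapped by a UTX peak, compared with 44.4% (42.5 to 46.2%) inside genes and 34.6% (32.6 to 36.7%) outside genes.

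Of 21887 protein-coding genes, 6834 had a Menin DMSO peak and 7982 a UTX MI-503 peak at a boundary. Both were found at 6210 genes, where independent lists would share 2492. From here on, Menin peaks are those in DMSO and UTX peaks those in MI-503, unless stated. These lists come from different treatments, so a gene with both was not shown to carry both proteins in the same cells. Differences between the lists join antibody with treatment. The 10 genes that ranked highest in both lists were Map2k1 (the kinase MEK1), Abcf1, Gcc1, Pdp1, Rrbp1, Fau, Mrpl49, Sde2, Smndc1 and Fbxw7. The Map2k1 peaks (chromosome 9, 64253444 to 64253982 for Menin, 64253407 to 64253879 for UTX) had fold enrichments of 26.2 and 31.6. The Rrbp1 peaks had 28.6 and 39.9, and the Pdp1 peaks had 37.9 and 31.7. Fau, a ribosomal protein gene, and Mrpl49 are neighbours on chromosome 19 and shared 1 peak of each kind, at 19.1-fold and 31.7-fold.

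Fewer genes had a boundary peak of 1 protein alone, 624 for Menin and 1772 for UTX. The highest such Menin peaks were at Mapk8, which encodes the stress kinase JNK1 (37.0-fold, chromosome 14, 33446965 to 33447607), Mtrf1l (21.1-fold), Garnl3 (19.7-fold), Prpsap2 (17.4-fold) and LOC115488529 (24.0-fold). A UTX peak overlapped the Menin peaks of Mtrf1l, Garnl3 and LOC115488529, with its summit outside the window, but not those of Mapk8 and Prpsap2. The highest UTX peaks at genes with UTX alone were at Bahd1 (27.8-fold), Klhl25 (24.5-fold), Gmfg (21.3-fold), Arl15 (22.4-fold) and Map7d1 (21.3-fold). Menin peaks overlapped the UTX peaks of Bahd1 and Gmfg, but not those of Klhl25, Arl15 and Map7d1. Over all such genes, the peak was overlapped by a peak of the other list for 23 of the 624 and 12 of the 1772.

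The HOXA cluster and its cofactors Meis1 and Pbx3 are the classical programme driven by MLL fusions. Of these 13 genes, 3 had a Menin DMSO peak and 6 a UTX MI-503 peak, which lay at percentiles 28.7 and 76.5 of 10000 random gene lists of that size. Pbx3 (10.97-fold and 19.2-fold), Hoxa3 (3.05-fold and 6.02-fold) and Hoxa11 (8.74-fold and 16.6-fold) had both, and Hoxa7 (11.2-fold), Hoxa10 (5.84-fold) and Meis1 (6.28-fold) had UTX alone. Across the cluster on chromosome 6, from 52135367 to 52280880, there were 3 Menin DMSO peaks, 12 UTX MI-503 peaks and none in the other lists. The 1 kb window missed peaks here. With a 3 kb window, 4 of the 13 genes had a Menin peak and 8 a UTX peak, at percentiles 37.8 and 92.2. A UTX peak inside Hoxa9 (52225948 to 52226298, 12.3-fold) lay 1246 bp from its boundary, and a Menin peak at Hoxa7 (52217429 to 52217636, 5.09-fold) lay 1036 bp from its boundary. Of 24 other genes known as MLL-fusion targets, 4 had a Menin peak and 7 a UTX peak, at percentiles 6.0 and 23.5. Elf1 and Runx1 had both, Gnaq had Menin alone, and Flt3, Myb, Jmjd1c and Myc had UTX alone. Mecom, Bcl2, Cdk6 and Mef2c had neither. With a 3 kb window, 6 of these 24 genes had a Menin peak and 10 a UTX peak, at percentiles 14.4 and 50.6.

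**Figure D3:**
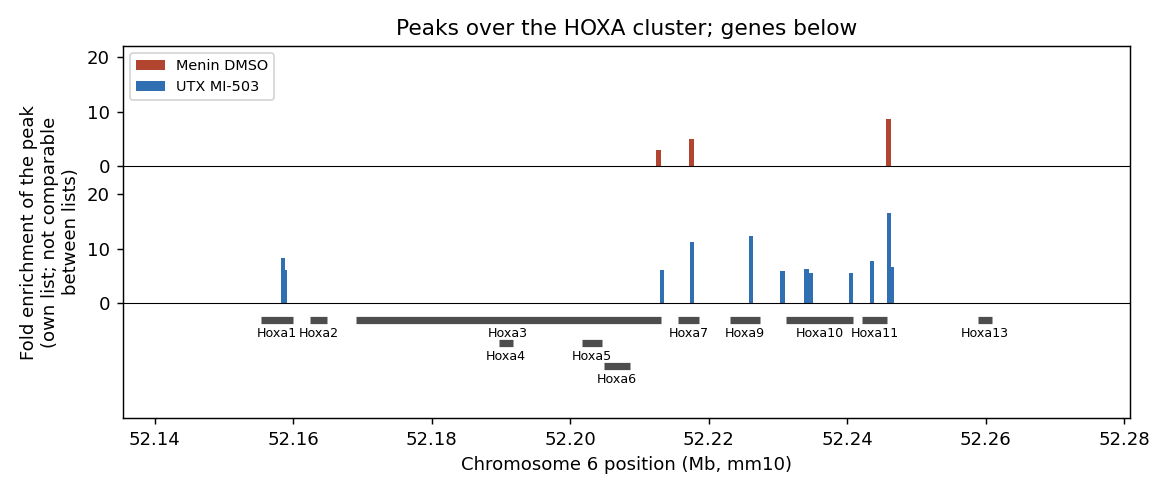
Fold enrichment of each Menin DMSO peak (upper) and UTX MI-503 peak (lower) over the HOXA cluster on chromosome 6 (mm10, in Mb), with the annotated genes as bars below. There are 3 Menin peaks, near Hoxa3, Hoxa7 and Hoxa11, and 12 UTX peaks; heights are comparable within a list only.

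Genes of cell cycle arrest often had both a Menin DMSO and a UTX MI-503 peak. Of 17 cell cycle inhibitors and tumour suppressors, 11 (64.7%) had a Menin peak and 14 (82.4%) a UTX peak, at percentiles 99.8 and 99.995. Of 20 housekeeping genes, 85% had a Menin peak and 85% a UTX peak. The random lists were drawn from all protein-coding genes. A high percentile, in this list or a later list, is thus not particular to the theme of the list. Cdkn2a (5.39-fold and 6.57-fold), Cdkn2b (6.96-fold and 10.9-fold), Cdkn2c (5.79-fold and 8.76-fold), Cdkn2d (14.6-fold and 24.7-fold), Rbl2, Trp53 and Btg1 (22.3-fold and 36.1-fold) had both. Cdkn1b and Rbl1 had UTX alone, Rb1 had Menin alone, and Cdkn1a and Cdkn1c had neither. Among 25 senescence-associated secreted factors, 5 had a Menin peak and 5 a UTX peak, at percentiles 11.4 and 4.14. With a 3 kb window, 9 (36%) had a Menin peak, at percentile 53.0. Tgfb1, Tnfrsf1a and Tnfrsf1b had both, while Il6, Il1a and Cxcl1 had neither.

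The mitotic genes listed are known to bind NF-Y, a factor that recognises CCAAT boxes, at their promoters. Of these 25 genes, 24 had a UTX MI-503 peak and 15 a Menin DMSO peak, at percentiles of 100 and 99.8. Ccna2 (8.45-fold and 17.0-fold), Ccnb2 (4.41-fold and 8.56-fold), Aurka (6.22-fold and 17.5-fold) and Cdc25c (6.54-fold and 9.40-fold) had both. Ccnb1 (7.77-fold), Cdk1 (14.2-fold), Cdc20 (8.04-fold), Cdc25b (5.25-fold), Plk1 (8.21-fold) and Aurkb (10.1-fold) had UTX alone, and Bub1b had neither. The NF-YA libraries of the series were not analysed here.

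Most metabolic and stress genes of the lists had a peak of each protein. Of 20 unfolded protein response genes, 19 had a Menin peak and 18 a UTX peak. Hspa5, the main chaperone of the endoplasmic reticulum, had both (8.24-fold and 28.0-fold), as did Xbp1 (5.09-fold and 16.7-fold), Atf4 (10.3-fold and 20.8-fold), Ddit3, Dnajb9 (17.5-fold and 40.5-fold), Herpud1 (11.4-fold and 39.9-fold), Pdia4, Pdia6 and Hsp90b1. Atf6 had Menin alone and Edem1 neither. Of these 20 genes, 5 also had a UTX DMSO peak, among them Hspa5, Herpud1 and Hsp90b1. Of 20 cholesterol synthesis genes, 16 had a Menin peak and 18 a UTX peak. Hmgcs1, Sqle (17.4-fold and 16.3-fold), Idi1, Lss (21.8-fold and 19.1-fold), Cyp51 and Dhcr7 had both, and Fdps had UTX alone. Both lists lay at the 100th percentile for both proteins, as did 20 housekeeping genes, of which 17 had a Menin peak and 17 a UTX peak. Gapdh had both (9.06-fold and 18.1-fold), Hprt Menin alone and Gusb UTX alone.

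The genes of the complexes themselves were among those covered. Of 23 MLL complex subunits and partners, 15 had a Menin peak and 17 a UTX peak, at percentiles 99.9 and 99.985. Kmt2a, which encodes MLL1 (6.72-fold and 17.6-fold), Kmt2b, Kmt2c, Kmt2d, which encodes MLL4 (10.9-fold and 31.2-fold), Setd1a, Men1 (5.52-fold and 7.66-fold), Wdr5, Ash2l and Paxip1 had both, and Setd1b had UTX alone. Kdm6a, which encodes UTX, had neither. Men1 also had a UTX DMSO peak.

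Among 28 myeloid differentiation genes, 8 had a Menin peak and 9 a UTX peak, at percentiles 39.0 and 32.0. Spi1, which encodes PU.1 (12.1-fold and 15.9-fold), Cebpa (5.63-fold and 6.99-fold), Cebpb, Csf2ra and Camp had both. Cebpd, Cebpe and Irf8 had UTX alone, and Cd68 and Egr1 Menin alone. Mpo, Elane, Lyz2 and Csf1r had neither. With a 3 kb window, 12 myeloid genes had a Menin peak and 13 a UTX peak, at percentiles 78.6 and 69.5. With a −log10 q of at least 5, these were 6 and 9, at percentiles 18.1 and 42.7. Of 18 genes of MHC class II and antigen presentation, 5 had a Menin peak and 7 a UTX peak, at percentiles 39.2 and 59.3. H2-DMa (12.4-fold and 39.3-fold), Rfxank, Rfxap, Tap1 and H2-D1 had both, B2m and H2-K1 had UTX alone, and Ciita, Cd74 and H2-Aa had neither. Of 20 interferon response genes, 6 had both peaks, Stat2, Irf1, Irf3, Irf9 and Socs1 among them, and 14, with Isg15, Ifit1 and Irf7 among them, had neither. Their shares with a Menin and a UTX peak lay at percentiles 46.7 and 28.1, and at 66.3 and 61.5 with a 3 kb window.

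Markers of other lineages were rarely covered. No hepatocyte marker among 20 had a peak of either protein, and no gene among 28 HOX genes outside the HOXA cluster had a Menin peak, while Hoxb13 and Hoxd1 had a UTX peak. Of 20 lymphocyte markers, Ebf1 and Cd3d had a Menin peak and none had a UTX peak. Of 20 genes each, the fibroblast list had 1 with Menin and 2 with UTX (Vim with both, Twist2 with UTX), the neuronal list had 1 and 3 (Syp with both, Grin1 and Grin2b with UTX), and the erythroid and megakaryocyte list had 3 and 4 (Tfrc and Nfe2 with both). Percentiles for these 6 lists lay between 0 and 6.23. With a 3 kb window, the erythroid and megakaryocyte list was no longer low for Menin, with 7 of 20 genes (35%) at percentile 48.98, and had 6 (30%) with UTX at percentile 14.7. That window also gave 5 neuronal markers with UTX, at percentile 6.44, 2 neuronal and 2 fibroblast markers with Menin, and 1 lymphocyte and 1 hepatocyte marker with UTX. With a −log10 q of at least 5, the fibroblast list and the other HOX genes each had 1 gene with UTX.

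**Figure D4:**
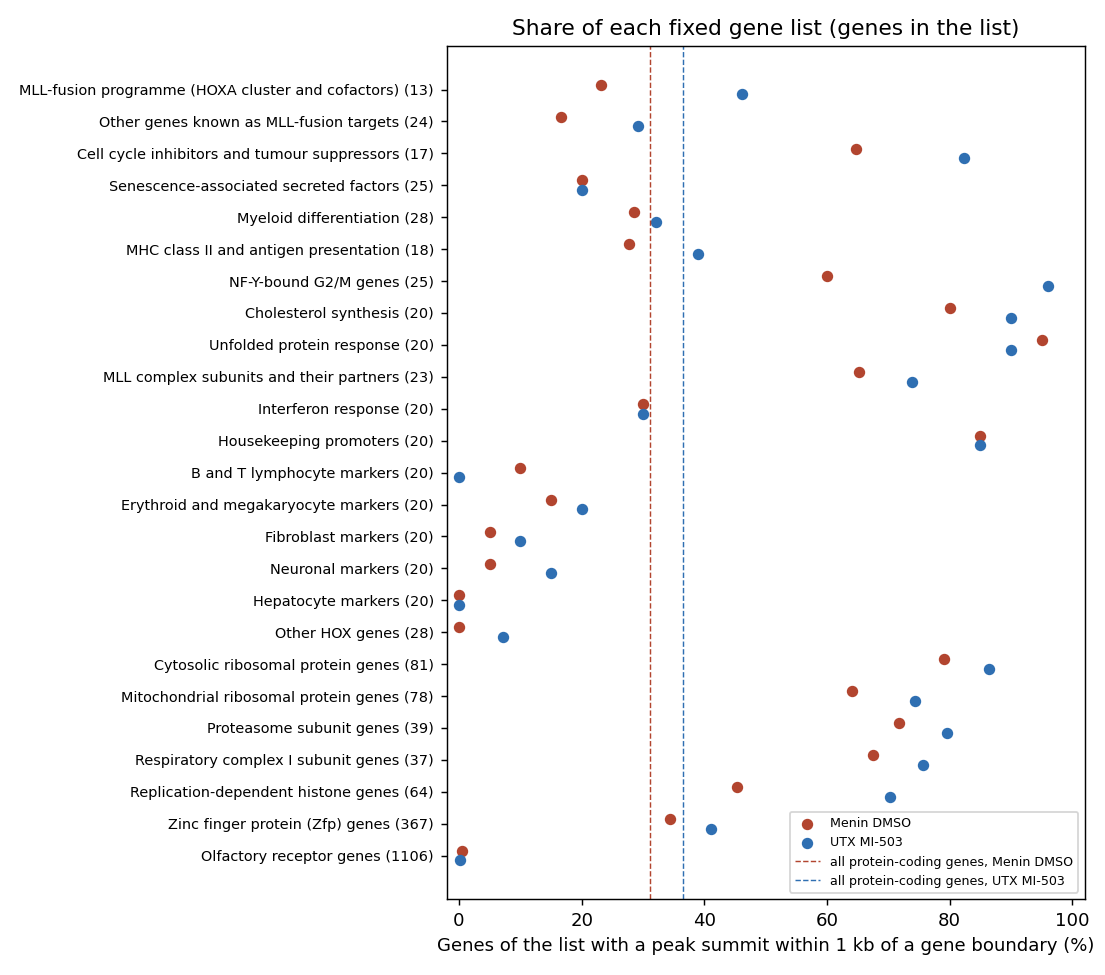
Share of each of the 25 gene lists with a Menin DMSO or UTX MI-503 peak within 1 kb of a gene boundary, in percent, with the number of genes in parentheses; dashed lines are the shares of all protein-coding genes, 31.2% and 36.5%. The G2/M list reached 96% for UTX and 60% for Menin.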

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

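Most tests in this part were chosen after the result they bear on was seen: those of depth, fragment length, gene boundaries and input-rich ground. The test of ranks in the UTX lists was written before its value was seen. The numbers of called Menin and UTX peaks differed in opposite directions between the treatments. From DMSO to MI-503, the number of Menin peaks changed by -11187 and that of UTX peaks by 14014. With 1 library per condition, this difference was not tested.

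The Menin list was 1399 times longer in DMSO than in MI-503. A shallower MI-503 library is argued against, since it held 1.65 times the reads of the DMSO library, and no less than 1.35 times by the pileup steps alone. The MI-503 list appears to have been built with shorter fragments, an inference from its narrowest peak, 62 bp against 179 bp. If fragments were spread evenly, 2629 of the 11195 Menin DMSO peaks (23.5%), rescaled to the depth and width of the MI-503 list, would still reach its lowest −log10 p of 13.6. That estimate rests on an assumed profile, so the fragment setting cannot be told apart from other causes. A weaker immunoprecipitation in this library and displacement of Menin by the drug, the contrast of the design, both stay open.

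The UTX list was 65.6 times longer in MI-503 than in DMSO. Depth is argued against here too, since the DMSO library held 1.55 times the reads of the MI-503 library, and no less than 1.14 times by the pileup steps alone. UTX DMSO peaks off input-rich ground mostly met high-ranking UTX MI-503 peaks. The median rank of the MI-503 peaks met was at the 97.0th percentile of that list, and 140 of 170 were in its highest 10%. This is consistent with weaker enrichment at the same places in DMSO, whether from less UTX on chromatin or from a less efficient immunoprecipitation, which this test does not separate. Menin DMSO peaks also overlapped 86.6% of all 217 UTX DMSO peaks, so these places were not particular to UTX. Rescaled to the depth and narrowest peak of the UTX DMSO list, 127 bp, 11177 of the 14231 MI-503 peaks would reach its lowest −log10 p of 7.53. As an assumed profile, this leaves the fragment setting open.

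Menin DMSO and UTX MI-503 peaks coincided far more often than random placements. Annotated gene boundaries alone are argued against. Of 3234 Menin peaks over 3 kb from any annotated boundary, 33.5% (exact 95% interval 31.9 to 35.2%) were overlapped, against at most 0.588% in random placements. Only the outer start and end of each gene were used, so start sites inside genes were not covered by this test. Strongly input-rich ground is argued against as the main source, since 5.42% of the overlapped Menin peaks had a background at least 3 times the lowest of the list. A milder excess of input reads, below that cutoff, was not tested. Open chromatin that any antibody would enrich was not tested and stays open, as does shared targeting of both proteins.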

How the results depend on the processing

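No paired analysis was possible with the 4 libraries analysed, because each condition has 1 library among them. The UTX pair labelled Nfya-WT was not analysed here. The alternatives matched on CpG content and those on CCAAT sites were not run for want of the genome sequence. Direction did not reverse in any alternative: Menin had more peaks in DMSO, and UTX in MI-503, at every threshold. Given the lengths of the lists this was bound to hold, since each alternative filters or merges the same lists. It does not test how the lists were called. The number of genes with both peaks stayed within 1.5 times of 6210 under all 6 alternatives. Requiring a −log10 q of at least 10 left 6396 Menin DMSO, 60 UTX DMSO and 6330 UTX MI-503 peaks, and a fold of at least 5 left 7176 Menin DMSO peaks; these fell by the filter's own construction. In what follows, the cause was not tested unless stated.

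The share of Menin DMSO peaks overlapped by UTX MI-503 was 54.2% with a reciprocal overlap of at least 50%, 64.4% with summits within 250 bp, 69.7% within 1 kb, 69.9% and 68.9% with −log10 q of at least 5 and 10, 62.3% with lists of equal length, and 65.3% without input-rich ground, a choice made after seeing the data. For UTX MI-503 peaks overlapped by Menin DMSO, the same settings gave 42.7%, 51.4%, 61.6%, 58.6%, 69.97%, 62.6% and 50.9%. The share of UTX DMSO peaks overlapped by UTX MI-503 was 13.8% with reciprocal overlap, the DMSO peaks being narrower (median 144 bp against 264 bp), and 30.4% with lists of equal length, which keeps 217 MI-503 peaks. Of the 8 Menin MI-503 peaks, 0% were overlapped with reciprocal overlap or lists of equal length. With a −log10 q of at least 10 the share was 0% of 7 peaks, since that filter removes the overlapped Chchd7 peak.

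Within 500 bp of a gene boundary lay 51.3% of Menin DMSO and 50.3% of UTX MI-503 peaks, and within 3 kb 64.6%, 67.8% and, for UTX DMSO, 74.2%. With all annotated genes the shares were 61.0% and 63.0%, and with −log10 q of at least 5 they were 60.7% and 62.9%. Without input-rich ground the UTX DMSO share was 78.1%. At 3 kb, the share with a UTX peak was 84.6% of mitochondrial ribosomal protein genes, and the share with a Menin peak was 59.4% of histone genes and 39.5% of Zfp genes. The wider windows hold more peaks by construction. Absolute depth is unknown, so a missing peak in the lists of 8 and 217 is not evidence that the protein was absent there.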

Other observations

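The tests of the G2/M list, the histone list and the X chromosome in this part were chosen after the shares were seen. Of the 7 families taken by symbol, 4 had a peak of each protein at most members. Of 81 cytosolic ribosomal protein genes, 64 had a Menin DMSO peak and 70 a UTX MI-503 peak. Of 78 mitochondrial ribosomal protein genes these numbers were 50 and 58, of 39 proteasome subunit genes 28 and 31, and of 37 respiratory complex I genes 25 and 28, each at the 100th percentile of random lists for both proteins. Rpl7a, Mrpl15, Psma5 and Ndufa10 were among the genes of these families with a peak. Zinc finger genes with Zfp symbols, 367 in all, had 126 and 151, at percentiles 90.4 and 96.8. Olfactory receptor genes, silent in most tissues, had 5 and 1 of 1106.

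Replication-dependent histone genes had a UTX peak at 45 of 64 and a Menin peak at 29, all 29 of them with a UTX peak. These genes are not independent, since 18 of the 29 shared their Menin peak, and 29 of the 45 their UTX peak, with another histone gene.

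Among genes with a UTX MI-503 peak, the G2/M list had fewer Menin peaks than other genes of like UTX rank. Of its 24 UTX-bound genes, 15 (62.5%) had a Menin DMSO peak, where draws matched on the UTX −log10 q gave 85.9% on average and a central range of 75 to 95.8%. The observed share lay at percentile 0.04 of 10000 draws, so a chance draw of genes of like UTX rank would rarely give it. Chance is not excluded, since the G2/M list was tested after its share was seen. The draws were also not matched on promoter type. Of the 18 lists with at least 5 UTX-bound genes, this was the only list outside the central range of its draws on the low side, and 0 lay outside on the high side. The UTX-bound histone genes lay at percentile 4.30, inside that range. A candidate explanation is that UTX reached mitotic genes by a route that Menin does not share. The lists differ in treatment as well as antibody, so an effect of the drug cannot be told apart from it. The NF-YA libraries, and the UTX libraries labelled Nfya-WT and Nfya-KO, bear on this and were not analysed here. No direct test was made.

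The X chromosome had few boundary peaks. Of 966 X-linked genes, 14.6% had a Menin DMSO peak, against 32.4% of autosomal genes, and 13.4% had a UTX MI-503 peak, against 38.0%. None of 1000 random sets of 966 autosomal genes had as low a share for either protein, the lowest being 27.0% and 32.6%. A chance draw of genes is thus argued against. A lower copy number of the X and its many germline gene families may both contribute, and neither was tested.

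The widest UTX MI-503 peak spanned 6060 bp on chromosome 17 (39842890 to 39848949), on a background 28.5 times the lowest of its list, over the same ground as the highest UTX DMSO peaks. The mitochondrial genome held 13 Menin DMSO and 5 UTX MI-503 peaks.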
